A study of Mus musculus with 9 samples.

How the data were processed

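Poly(A) RNA of mouse kidney was sequenced as strand-specific paired-end libraries, 3 mice in each of 3 groups (saline, LPS, LPS+Tβ4). The submitters' processing notes list cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR (the last 2 without a version) and the genome build GRCm38, with no role for any of them. The counting program and the annotation release are not given in the sources used here. The deposited table holds, for 34310 Ensembl genes, a raw count and an FPKM value in each of the 9 libraries, both made by the authors. The count columns are whole numbers that sum to 53 to 62 M per library. The annotation in the table gives gene symbols, positions, KEGG pathways and Gene Ontology terms, and no other source of names was used.

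The test planned before the data were examined was limma on log2(FPKM + 1), with a count test to replace it if the table held counts. It did, so counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, a quasi-likelihood fit of all 9 libraries with a mean per group and no covariate, and a 2-sided test of each of 3 comparisons. The SE of a change is its size divided by the square root of the F statistic. Genes with a mean FPKM of at least 0.5 over the 9 libraries were kept (15015), and p-values were adjusted over them by the Benjamini-Hochberg method, with 0.05 as the threshold. Of 38 gene lists for pathways, kidney cell types, outside tissues and controls fixed at the same time, 33 with at least 5 measured members were tested with camera (limma 3.58.1, preset correlation 0.01), beside camera with an estimated correlation and fry, adjusted over the lists. Counts adjusted over the list alone were made for each list. KEGG and Gene Ontology terms of 10 to 500 tested genes were tested with the hypergeometric test on the annotated tested genes, and KEGG pathways with camera as well.

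Genes were named by a rule fixed at the same time. It took the 8 largest rises and the 8 largest falls among genes that passed, whose group ranges did not overlap, with a mean FPKM of at least 1 and a proper symbol, some of them left out for length. It added up to 4 members with the smallest adjusted p of each list described, and always Tmsb4x, Havcr1, Lcn2, Il6, Tnf, Il1b, Mapk3, Mapk8, Mapk14, Fos and Jun. Exceptions are marked in the text, and some results withheld for evaluation are not reported here.

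Library totals set the depth. A gene absent from a group was given a floor of 3 counts over its 3 libraries together. Same-numbered libraries of different groups were no more alike than others, so the replicate numbers were not used as pairs; the labels give no batch or date.

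The chain was tested on simulated data with the mean levels and dispersions of the 9 libraries. With 200 genes changed, edgeR recovered 0% of those changed 1.5-fold, 6.06%, 5.97% and 8.77% of those changed 2-fold and 55.1%, 58.8% and 62.5% of those changed 4-fold in the 3 comparisons, with 4, 3 and 5 false calls. Camera called a list raised 2-fold in 10 of 10 draws, with 0.3 other lists per draw.

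Alternatives covered the expression filter (none, a mean FPKM of 5, filterByExpr), the scale and test (limma on FPKM with pseudocounts of 0.1 and 1, on TPM, after quantile normalization and with array weights; DESeq2 1.42.0), median-of-ratios scaling, dominant genes left out, no abundance trend, robust estimation, a fit of the 6 libraries compared, a replicate block, a 2-fold minimum, terms for urothelial transcripts, genes of neural terms left out, and each library left out in turn. FPKM alternatives change the test along with the scale. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.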

Results

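Kidney RNA was sequenced from 9 mice in 3 groups of 3: mice given saline, mice given lipopolysaccharide (LPS, the endotoxin of Gram-negative bacteria), and mice given LPS with thymosin β4 (LPS+Tβ4), a small peptide that binds monomeric actin. Each library came from 1 mouse, and the labels give no dose, time, route, sex or strain. The saline libraries held 56.6, 58.9 and 59.5 M counts, the LPS libraries 58.1, 53 and 57.9 M, and the LPS+Tβ4 libraries 62, 60.7 and 60.2 M. Of 34310 genes in the table, 15015 passed the expression filter and were tested. Group levels below are counts per M (CPM) after TMM scaling, as mean ± SD (n = 3). Changes are log2 fold changes ± SE from edgeR.

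The comparison of LPS with saline asked what endotoxin did to the kidney transcriptome. In edgeR, 21 of 30 tubular injury genes, 22 of 24 acute-phase genes and 39 of 39 interferon-stimulated genes rose, and 24 of 37 proximal tubule genes and 23 of 31 oxidative phosphorylation genes fell. The falls of the last 2 lists passed camera at its preset correlation only (adjusted p = 0.22 and 0.38 with an estimated correlation). Lcn2, which encodes the secreted injury marker NGAL, rose from 36.8 ± 2.35 to 6270 ± 2910 CPM, a change of 7.41 ± 0.58 (adjusted p = 8.6e-05). Havcr1, which encodes the tubular injury marker KIM-1, rose from 5.67 ± 2.53 to 859 ± 247 CPM (7.24 ± 0.60, adjusted p = 1e-04). In the other direction, Slc2a2, the glucose transporter GLUT2 of the proximal tubule, fell from 216 ± 37.8 to 11.8 ± 3.18 CPM (-4.20 ± 0.27, adjusted p = 4.3e-05). In GRCm38 coordinates Lcn2 (ENSMUSG00000026822) lies on chromosome 2 at 32384633 to 32387797, Havcr1 (ENSMUSG00000040405) on chromosome 11 at 46735080 to 46779578, and Slc2a2 (ENSMUSG00000027690) on chromosome 3 at 28697903 to 28731359.

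All 39 measured interferon-stimulated genes rose, with a median change of 4.01 (camera adjusted p = 1.7e-56, and adjusted p = 0.014 with an estimated correlation). Among them, the antigen-processing transporter Tap1 rose from 11.7 ± 1.49 to 314 ± 65.4 CPM, the immunoproteasome subunit Psmb8 rose by 4.86, and the transcription factor Irf7 by 4.74. Of 32 cytokines and chemokines, 21 rose and none fell at the adjusted threshold in edgeR (22 and 0 adjusted over the list alone), with a median of 3.85 (camera adjusted p = 8.9e-12, and adjusted p = 0.058 with an estimated correlation). The neutrophil chemokine Cxcl5 rose from 0.389 ± 0.0447 to 71.9 ± 7.26 CPM, and Csf3, Lif, Il6 and Tnf rose by 6.16, 6.82, 6.78 and 4.45. Il1b stood at 0.726 ± 0.249 CPM in saline and 1.79 ± 0.777 CPM in LPS and did not pass the test (adjusted p = 0.081). Of 33 genes of TLR4 and NF-kB signalling, 26 rose and none fell (median 1.48, camera adjusted p = 6.3e-15, and adjusted p = 0.051 with an estimated correlation), among them Bcl3 (3.86), Birc3 (3.85) and Nfkbiz (3.63). Acute-phase and complement genes had a median of 4.48, with 22 of 24 raised (camera adjusted p = 5.3e-22, and adjusted p = 0.049 with an estimated correlation), and Socs3, a feedback inhibitor of cytokine receptors, rose by 5.77. In the tubular injury list, 21 of 30 rose (22 adjusted over the list alone), with a median of 2.49 (camera adjusted p = 7.6e-15, and adjusted p = 0.014 with an estimated correlation). The fibrinogen chain Fga rose from 38.7 ± 8.14 to 4110 ± 2680 CPM, and Sox9, a transcription factor of tubular repair, rose by 6.28. Of 10 neutrophil genes, 9 rose (10 adjusted over the list alone; median 5.03, camera adjusted p = 8e-06, and adjusted p = 0.1 with an estimated correlation), with S100a8 at 0.226 ± 0.0624 CPM in saline and 9.65 ± 4.64 CPM in LPS.

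Markers of most epithelial segments fell. Of 37 proximal tubule genes, 24 fell and none rose (28 fell adjusted over the list alone), with a median of -1.93 (camera adjusted p = 8.9e-12, and adjusted p = 0.22 with an estimated correlation). The endocytic receptor megalin, Lrp2, fell from 2150 ± 319 to 199 ± 85.2 CPM, and Slc47a1, an exporter of organic cations, from 653 ± 54.2 to 66.1 ± 14.5 CPM. Gatm, which makes guanidinoacetate for creatine synthesis, and Keg1, a glycine N-acyltransferase-like gene, fell by 5.99 and 5.61 on the log2 scale. Of 9 loop of Henle genes, 7 fell (camera adjusted p = 0.00031, and adjusted p = 0.22 with an estimated correlation), with the Na-K-Cl cotransporter Slc12a1 down from 734 ± 277 to 25.8 ± 17.7 CPM and Egf at -4.59. Of 9 distal convoluted tubule genes, 8 fell (camera adjusted p = 9.7e-07, and adjusted p = 0.1 with an estimated correlation), including Slc8a1 (-4.73) and Klhl3 (-3.41). Of 10 intercalated cell genes, 7 fell (camera adjusted p = 2.4e-06, and adjusted p = 0.091 with an estimated correlation), including the proton pump subunit Atp6v1b1 (-3.95) and the anion exchanger Slc4a1 (-4.61). Of 31 nuclear-encoded genes of oxidative phosphorylation, 23 fell and none rose, with a median of -0.83 (camera adjusted p = 1.7e-06, and adjusted p = 0.38 with an estimated correlation). Ndufs1, a complex I subunit, fell from 274 ± 25.1 to 91.1 ± 14.2 CPM. Genes on the mitochondrial chromosome held 16.2%, 12.9% and 13.9% of the counts in the saline libraries and 7.64%, 10.6% and 8.89% in the LPS libraries. Pseudogenes held 4.66% to 5.97% and 2.99% to 3.84%, and the 20 most abundant genes 20% to 26% and 14.8% to 19.8%. Whether these shares bear on the fall was not tested. Fatty acid oxidation genes went both ways, 11 down and 5 up of 30 (median -0.44, camera adjusted p = 0.14). The oxidation enzyme Acadm and the coactivator Ppargc1a fell by 1.71 and 2.05 on the log2 scale, whereas Pdk4 rose by 4.25. Acot1, Acot2 and Acadl, named after their values were seen, were also raised.

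Genes of MAPK signalling, the pathway in the title of the series, rose in part. Of 44 MAPK cascade genes (kinases with their Ras-family and adaptor activators), 16 rose and 4 fell, the same counts as adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.0054, and adjusted p = 0.058 with an estimated correlation). Map3k8, the kinase Tpl2 that links endotoxin receptors to ERK, rose from 2.46 ± 0.719 to 30.2 ± 15.4 CPM, and Mapk7 (ERK5) and Nras rose by 1.86 and 1.63. The p38 kinase Mapk14 fell from 132 ± 4.67 to 70.8 ± 6.61 CPM (-0.90 ± 0.13, adjusted p = 0.0011). The other 3 that fell, named after their values were seen, were Map2k2, Map3k4 and Map3k5. Mapk3 (ERK1) did not pass, with 0.19 (adjusted p = 0.42). The JNK gene Mapk8 rose by 0.47 (adjusted p = 0.04), a call that 14 of its 26 alternatives ended. Among these were the omission of any single saline library, of LPS replicate 2 or 3, or of LPS+Tβ4 replicate 1 or 2; its adjusted p ranged from 0.009 to 0.11. Of 17 phosphatases and feedback inhibitors of the cascade, 6 rose and Dusp9 fell (-2.85), and the list did not pass (camera adjusted p = 0.06). Downstream, 24 of 27 immediate-early and AP-1 genes rose and none fell, with a median of 2.26 (camera adjusted p = 8.9e-12, and adjusted p = 0.091 with an estimated correlation). Jun rose from 21.8 ± 4.56 to 104 ± 9.76 CPM and Fos from 5 ± 1.89 to 43.7 ± 24.2 CPM. Fosl1 had no count in any saline library and 18.9 ± 3.76 CPM in LPS, at least 1010-fold higher than the floor of 3 counts over the 3 saline libraries (0.0186 CPM). It overlaps Ccdc85b on the opposite strand, and how the counting treated strand is not given. In the annotation carried by the table, 76 of 226 KEGG MAPK pathway genes rose and 37 fell (median 0.26, adjusted p = 0.011 over 303 pathways, and unadjusted p = 0.039 with an estimated correlation). Tmsb4x, which encodes thymosin β4 itself, stood at 279 ± 55.2 CPM in saline and 705 ± 517 CPM in LPS (adjusted p = 0.17).

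In all, 6473 of 15015 genes differed between LPS and saline by edgeR, 3144 higher and 3329 lower. Group ranges did not overlap for 54.3% of the tested genes, where chance gives 10%. Higher genes were enriched in immune system process (153 of 309 genes, 68.4 expected by chance, adjusted p = 2.6e-23), and lower genes in mitochondrial inner membrane (206 of 383 genes, adjusted p = 3.1e-35). Floors here cover counting error only, and nothing beyond the labels describes the replicates.

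**Figure D1:**
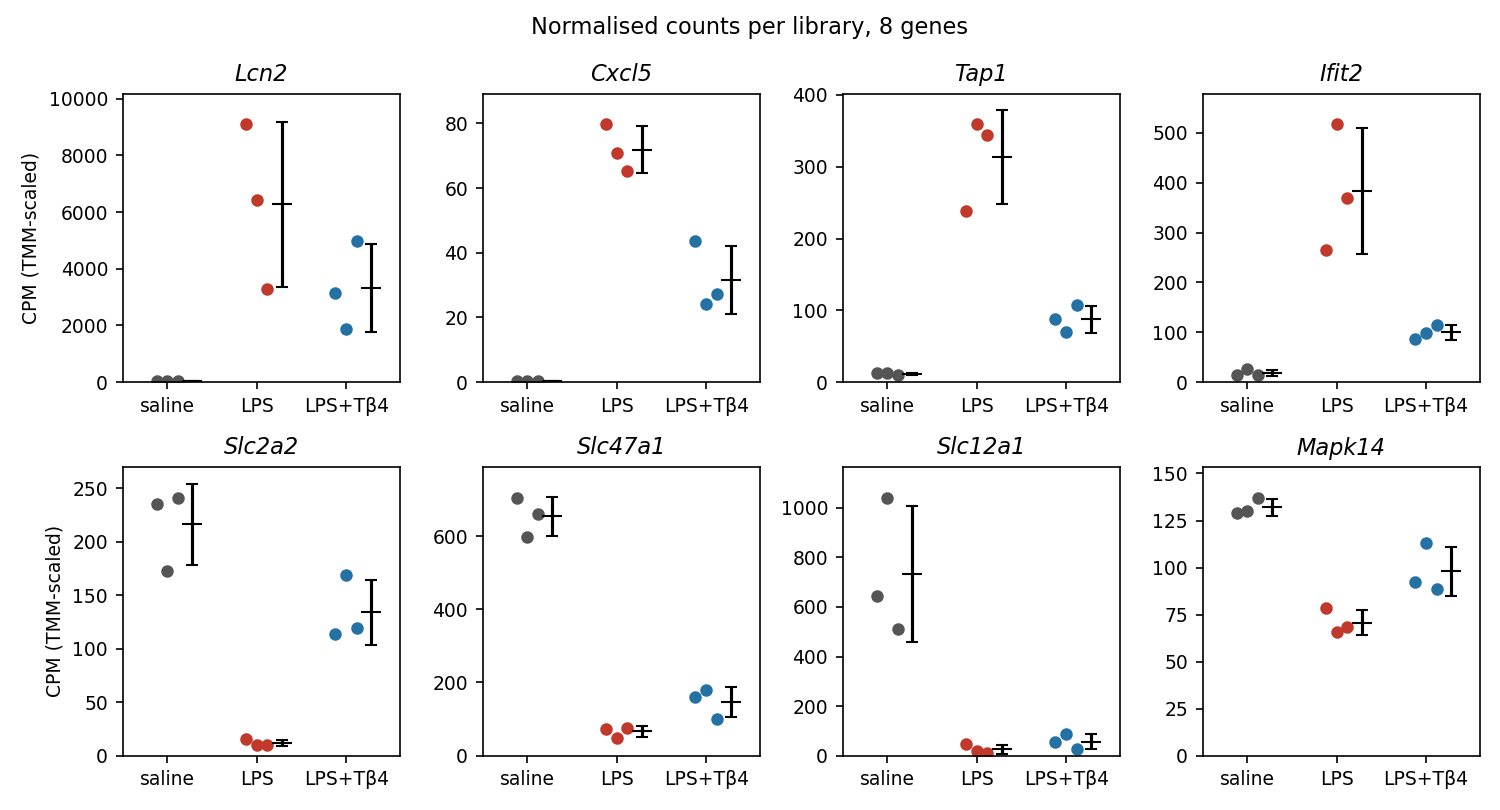
Normalised counts (CPM, linear axes from 0) of 8 genes in each of the 9 libraries, with each point 1 library and the bars the group mean ± SD (n = 3). Slc2a2 averaged 216 CPM in saline, 11.8 in LPS and 134 in LPS+Tβ4, whereas Mapk14 averaged 132, 70.8 and 98.2 CPM.

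The comparison of LPS+Tβ4 with LPS asked what thymosin β4 changed in endotoxin-treated mice. In edgeR, 21 of 39 interferon-stimulated genes were lower, and the injury markers Havcr1 and Lcn2 did not pass. The interferon list passed camera at its preset correlation only (adjusted p = 0.13 with an estimated correlation). Slc2a2 rose from 11.8 ± 3.18 to 134 ± 30.2 CPM (3.51 ± 0.26, adjusted p = 0.0026). Tap1 fell from 314 ± 65.4 to 87.9 ± 19.1 CPM (-1.83 ± 0.22, adjusted p = 0.0095). Havcr1 was 859 ± 247 CPM in LPS and 853 ± 448 CPM in LPS+Tβ4 (-0.01 ± 0.46, adjusted p = 0.99), and Lcn2 was 6270 ± 2910 and 3320 ± 1560 CPM (-0.91 ± 0.44, adjusted p = 0.24).

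Of 39 interferon-stimulated genes, 21 fell and none rose (28 fell adjusted over the list alone), with a median of -1.29 (camera adjusted p = 2e-25, and adjusted p = 0.13 with an estimated correlation). Ifit2 fell from 384 ± 126 to 99.9 ± 14.7 CPM, and Cmpk2, Xaf1 and Mx1 fell by 1.45, 1.36 and 2.16 on the log2 scale. Outside the list, Cd274, the checkpoint ligand PD-L1, fell from 166 ± 83.9 to 26.4 ± 11.3 CPM, and the guanylate-binding protein genes Gbp4 and Gbp9 fell by 2.43 and 2.19 on the log2 scale. Of 33 TLR4 and NF-kB genes, Birc3 alone passed over all genes (-1.21, adjusted p = 0.031) and 5 fell adjusted over the list alone, with a list median of -0.41 (camera adjusted p = 0.00016, and adjusted p = 0.36 with an estimated correlation). The LPS co-receptor Cd14 was 1240 ± 890 CPM in LPS and 273 ± 122 CPM in LPS+Tβ4 (adjusted p = 0.063). Of 32 cytokines and chemokines, Cxcl5 fell (-1.19, adjusted p = 0.024), and the list did not pass (camera adjusted p = 0.35). Ccl6, Ccl9 and Il1b rose (1.67, 1.89 and 2.19, adjusted p = 0.032, 0.046 and 0.049). The call of Cxcl5 was ended by 5 of its 27 alternatives, that of Ccl6 by 9 of 27 and that of Ccl9 by 15 of 27. That of Il1b was ended by 18 of 26, among them the omission of any single library. Il6 and Tnf had changes of -0.41 (adjusted p = 0.79) and -0.35 (adjusted p = 0.83). The adhesion molecules moved apart, Icam1 down by 1.04 on the log2 scale and Vcam1 up by 1.21, the latter the only gene of 30 in the tubular injury list to pass (camera adjusted p = 0.28 for that list).

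Of 37 proximal tubule genes, 3 rose and none fell, adjusted over all genes as over the list alone: Slc2a2, Slc47a1 (66.1 ± 14.5 to 147 ± 40.7 CPM, adjusted p = 0.034) and the urate transporter Slc22a12 (350 ± 76.7 to 837 ± 258 CPM, adjusted p = 0.034). DESeq2 called 10 of the 37 higher and 3 lower, and limma on log2(FPKM + 1) 8 higher and 0 lower. The list median was 0.32 (camera adjusted p = 0.005, and adjusted p = 0.66 with an estimated correlation). It was 1.11 with only replicates 1 and 2 of both groups and -0.82 with only replicate 3. Klhl3 and Slc8a1 rose among 9 distal convoluted tubule genes by 1.69 and 1.57 (5 adjusted over the list alone; list median 0.77, camera adjusted p = 0.00071, and adjusted p = 0.4 with an estimated correlation). Atp6v1b1 (2.19) and Insrr (1.87, overlapped by Pear1 on the opposite strand) rose among 10 intercalated cell genes (5 adjusted over the list alone; list median 0.62, camera adjusted p = 5e-04, and adjusted p = 0.36 with an estimated correlation). Hsd11b2, the enzyme that shields the mineralocorticoid receptor from glucocorticoids, was the 1 of 10 principal cell genes that passed, rising from 11.9 ± 2.3 to 61.2 ± 17.4 CPM (list camera adjusted p = 0.16). Ptpro passed among 10 podocyte genes (1.44), and Podxl was at the threshold without passing (0.96, adjusted p = 0.05). The podocyte median was 0.73 (camera adjusted p = 0.0062, and adjusted p = 0.51 with an estimated correlation). With only replicates 1 and 2 of both groups it was 0.95, and with only replicate 3 it was 0.13. Of 30 fatty acid oxidation genes, 4 rose and none fell, among them Cyp4a14 (55.2 ± 27 to 298 ± 81.4 CPM), Decr1 and Eci1 (7 rose adjusted over the list alone; median 0.36, camera adjusted p = 5e-04, and adjusted p = 0.61 with an estimated correlation). The median was 0.69 with only replicates 1 and 2 of both groups and -0.26 with only replicate 3. None of 31 oxidative phosphorylation genes passed in edgeR or over the list alone (median 0.14, camera adjusted p = 0.28). At an unadjusted p under 0.05, 2 were higher, and 0 by DESeq2 or limma. Their median was 0.41 with only replicates 1 and 2 of both groups and -0.46 with only replicate 3.

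Few transcripts of MAPK signalling passed. Of 44 MAPK cascade genes, Grb2 and Nras fell by 0.46 and 0.56 on the log2 scale (adjusted p = 0.036 and 0.038). Adjusted over the list alone, 0 rose and 2 fell. The list median was -0.18 (camera adjusted p = 0.028, and adjusted p = 0.25 with an estimated correlation). The call of Grb2 was ended by 16 of its 27 alternatives and that of Nras by 14 of 28. Both were lost without any single saline library, LPS replicate 2 or 3, or LPS+Tβ4 replicate 1 or 2. Their adjusted p reached 0.3 and 0.17. In the same list DESeq2 called 2 higher and 6 lower, and limma on log2(FPKM + 1) called 1 lower. Mapk3, Mapk8 and Mapk14 did not pass, at -0.02 (adjusted p = 0.97), -0.55 (adjusted p = 0.074) and 0.47 (adjusted p = 0.067). No member of the phosphatase list or the immediate-early list passed in edgeR, over all genes or over the list alone (medians -0.35 and -0.34, camera adjusted p = 0.13 and 0.088). At an unadjusted p under 0.05, 4 and 3 were lower, by DESeq2 2 and 1, and by limma on log2(FPKM + 1) 0 and 1. In edgeR Fos was at -0.84 (adjusted p = 0.5) and Jun at 0.56 (adjusted p = 0.22). Fosl1 was 18.9 ± 3.76 CPM in LPS and 2.95 ± 2.72 CPM in LPS+Tβ4 (-2.68 ± 0.67, adjusted p = 0.066). Of the 226 KEGG MAPK pathway genes, 9 rose and 8 fell, with a median of -0.09 (adjusted p = 0.32, and unadjusted p = 0.28 with an estimated correlation). These are RNA levels, and phosphorylation of the kinases was not measured. Tmsb4x was 705 ± 517 CPM in LPS and 404 ± 340 CPM in LPS+Tβ4 (adjusted p = 0.53).

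Transcripts of other tissues differed between the groups too. The myelin gene Mobp stood at 1.27 ± 0.294 CPM in saline, 1.98 ± 1.17 CPM in LPS and 56.9 ± 5.44 CPM in LPS+Tβ4 (4.84 ± 0.42 against LPS, adjusted p = 0.0049). The neuronal kinase gene Camk2a (3.69), the astrocyte gene Gfap (3.71), the myelin gene Mag (3.81) and the neuronal calcium sensor Vsnl1 (4.07) rose as well. Genes with neural terms made up 17% of the tested genes and 28.3% of those higher in LPS+Tβ4 (191 of 675). The higher genes were enriched in ion transport (49 of 350 genes, 17.4 expected by chance, adjusted p = 8.1e-08) and synapse (57 of 486 genes, 24.1 expected, adjusted p = 1.2e-06). Lower genes were enriched in immune system process (28 of 309 genes, 7.79 expected, adjusted p = 7.4e-06) and defense response to virus (17 of 132 genes, 3.33 expected, adjusted p = 3.8e-05). All 5 measured erythroid genes (Hbb-bs, Hbb-bt, Hba-a1, Hba-a2 and Alas2) fell, with a median of -1.52 (camera adjusted p = 9.7e-12, and adjusted p = 0.13 with an estimated correlation). Hbb-bs was 247 ± 10.7, 230 ± 45.1 and 76.8 ± 12.4 CPM in saline, LPS and LPS+Tβ4, and the paired globin genes can share reads. Summed transcripts of 5 urothelial genes were 72.9, 84.1 and 0.784 CPM in LPS replicates 1, 2 and 3 and 0.695, 0.839 and 90.4 CPM in the LPS+Tβ4 replicates, so that they split each group.

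In all, 1025 genes differed between LPS+Tβ4 and LPS by edgeR, 675 higher and 350 lower, and ranges did not overlap for 26.3% of the tested genes, where chance gives 10%. The share of higher genes among them was 65.9%, against 83.5% (582 and 115) with TPM and 77.8% (831 and 237) with dominant genes left out. The count moved with the libraries fitted. It was 3 when the 6 libraries compared were fitted alone, 2442 by DESeq2 and 668 without the genes of neural terms. Without 1 library it was 454, 402 and 341 (saline replicates 1, 2 and 3), 2672, 102 and 462 (LPS) and 198, 68 and 935 (LPS+Tβ4). Of 51 genes tracked in this comparison that passed, 7 kept their call without each single library (Slc2a2, Hsd11b2, Tap1, Hbb-bs, Camk2a, Mobp and Vsnl1). The other 44 lost it without at least 1, from 3 without LPS replicate 1 to 43 without LPS+Tβ4 replicate 2 (20, 23 and 23 without the saline replicates, 41 and 25 without LPS replicates 2 and 3, 36 and 13 without LPS+Tβ4 replicates 1 and 3).

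**Figure D2:**
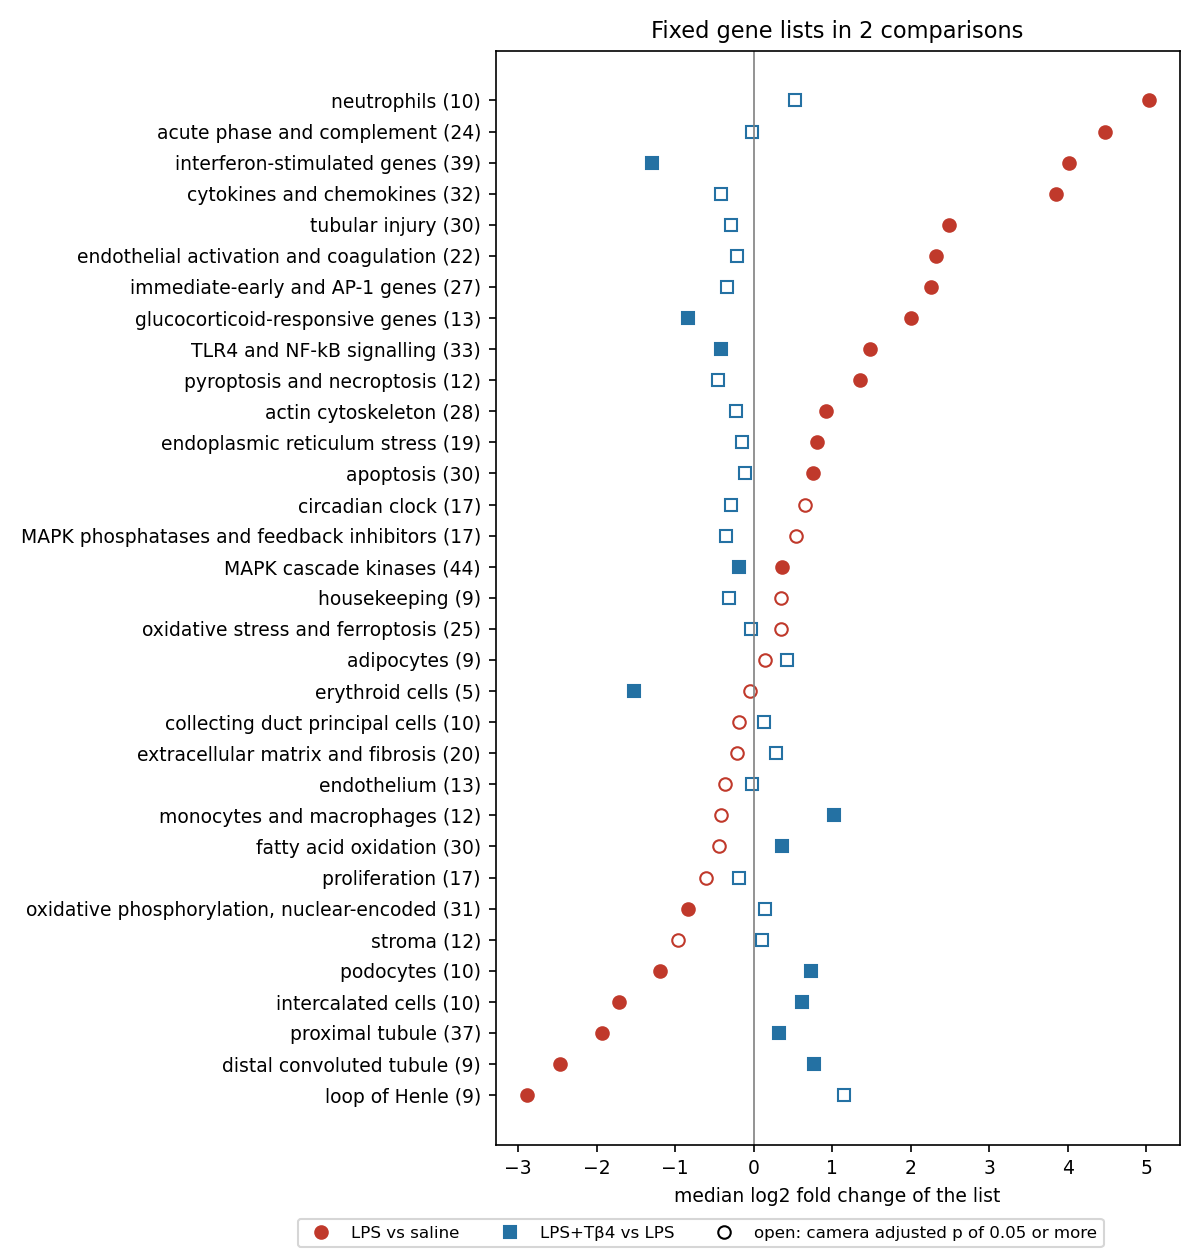
Median log2 fold change of each gene list in LPS against saline (circles) and in LPS+Tβ4 against LPS (squares), with the number of measured genes in brackets and filled symbols for a camera adjusted p under 0.05. Interferon-stimulated genes stood at 4.01 and -1.29, tubular injury genes at 2.49 and -0.29.

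**Figure D3:**
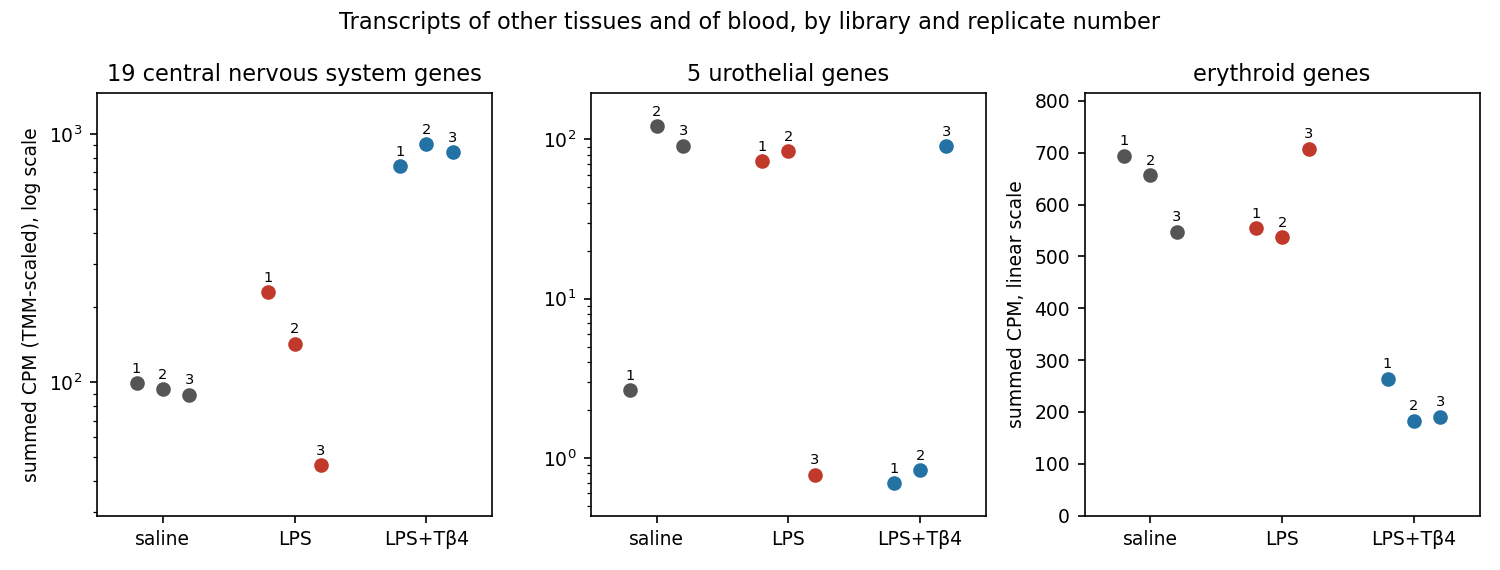
Summed CPM per library of 19 central nervous system genes and 5 urothelial genes (log axes) and of the erythroid genes (linear axis), each point 1 library with its replicate number. The central nervous system sum was 742 to 910 CPM in LPS+Tβ4 and at most 230 CPM elsewhere, and the urothelial sum was above 70 CPM in 5 libraries and below 3 CPM in the other 4.

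The comparison of LPS+Tβ4 with saline asked what remained of the endotoxin response. The injury and acute-phase response was still present: Havcr1 was 853 ± 448 CPM against 5.67 ± 2.53 CPM in saline (7.23, adjusted p = 0.00028), Lcn2 rose by 6.50 (adjusted p = 0.00031) and Fga by 6.56 (adjusted p = 0.00041). Of 30 tubular injury genes, 21 rose (median 2.33, camera adjusted p = 1.7e-21, and adjusted p = 0.01 with an estimated correlation), as did 21 of 24 acute-phase genes (median 4.01, camera adjusted p = 4.8e-34, and adjusted p = 0.01 with an estimated correlation). Of 39 interferon-stimulated genes, 35 rose, with a median of 2.67 (camera adjusted p = 1.5e-51, and adjusted p = 0.01 with an estimated correlation); Tap1 and Ifit2 rose by 2.91 and 2.47. All 10 neutrophil genes rose (median 5.63, camera adjusted p = 4e-10, and adjusted p = 0.085 with an estimated correlation). Of 37 proximal tubule genes, 19 fell (median -1.80, camera adjusted p = 1.2e-11, and adjusted p = 0.21 with an estimated correlation): Lrp2 fell by 2.83 and Slc47a1 by 2.16 on the log2 scale, while Slc2a2, at 134 ± 30.2 against 216 ± 37.8 CPM, did not pass (adjusted p = 0.068). Of 31 oxidative phosphorylation genes, 17 fell (median -0.75, camera adjusted p = 7.8e-08, and adjusted p = 0.31 with an estimated correlation). Of 44 MAPK cascade genes, 10 rose and 2 fell, Mapk14 and Map3k5 (median 0.15, camera adjusted p = 0.045, and adjusted p = 0.14 with an estimated correlation). The KEGG MAPK pathway had 57 of 226 genes raised and 20 lowered (median 0.17, adjusted p = 0.012, and unadjusted p = 0.052 with an estimated correlation).

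In all, 3617 genes differed between LPS+Tβ4 and saline by edgeR, 1852 higher and 1765 lower, and ranges did not overlap for 50.9% of the tested genes (10% by chance). The count was 2269, 2386 and 2183 without saline replicate 1, 2 or 3, and 2119 without LPS+Tβ4 replicate 1.

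The last question was how far LPS+Tβ4 moved the endotoxin response back towards saline. Of the genes that differed between LPS and saline, 838 changed in the opposite direction between LPS+Tβ4 and LPS: 324 raised by LPS and lower with thymosin β4, such as Tap1, Ifit2 and Cxcl5, and 514 lowered by LPS and higher with it, such as Slc2a2, Klhl3 and Atp6v1b1. Another 26 moved further from saline, such as Vcam1. Independent lists of the same sizes would share 73.3 and 150 genes, but both comparisons use the same LPS libraries. Over the genes that differed between LPS and saline, the least-squares slope of the LPS+Tβ4 change on the LPS change was 0.729. It was 0.747, 0.595 and 0.78 for the 3 LPS+Tβ4 libraries (SD 0.098). In 30 simulated sets with an unchanged LPS+Tβ4 group the median slope was 0.995. That group was drawn around the mean of the same LPS libraries, which puts the slope near 1 by construction. Error in the LPS libraries is left out, so 0.995 is not a chance level for the slope. Next, 1 LPS library was kept for the second comparison and the other LPS libraries for the first. The slopes were then 0.688, 0.68 and 0.654 for LPS replicates 1, 2 and 3. They were taken on the change of the 1 library kept, whose noise lowers a slope without any effect of treatment. No value for an unchanged group was made for them, so these slopes are not a replication of 0.729. The counts were 21, 3 and 386, but a single LPS library has no spread of its own and the spread came from the other groups, so these counts are not a replication of the 838. In these fits 73.5%, 80.5% and 71.1% of the genes that differed between LPS and saline went the opposite way between LPS+Tβ4 and LPS. The 3 shared libraries cannot be divided more evenly. The count of 838 was 2 in the 6 libraries fitted alone. Without 1 library it was 335, 305 and 243 (saline replicates 1, 2 and 3), 2149, 78 and 364 (LPS) and 154, 54 and 779 (LPS+Tβ4).

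**Figure D4:**
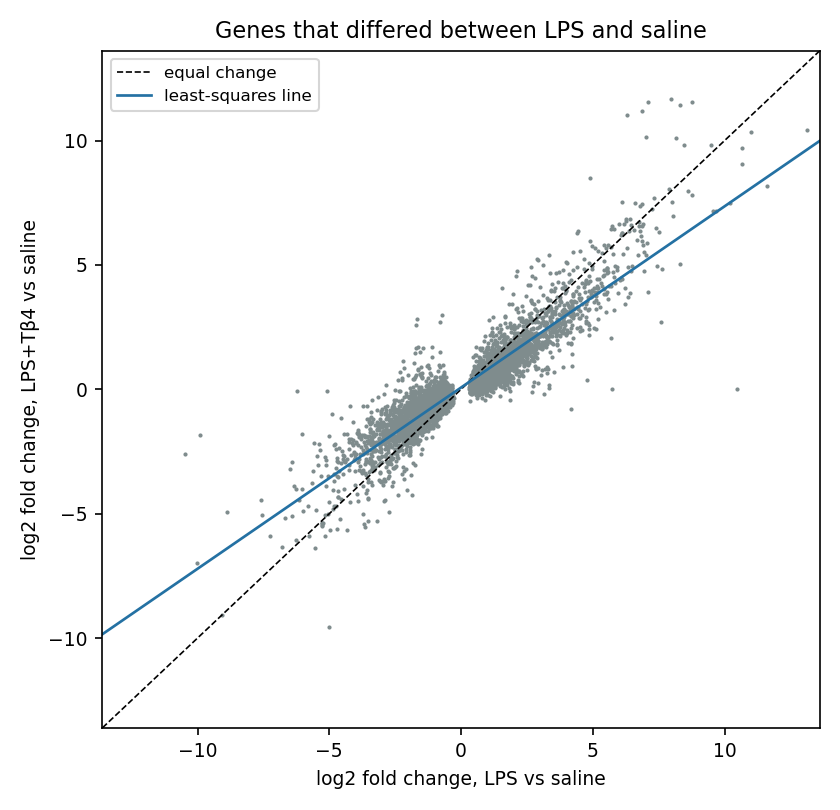
Log2 fold change of LPS+Tβ4 against saline, plotted on that of LPS against saline, for the 6473 genes that differed between LPS and saline, each point 1 gene. The dashed line marks equal change and the solid line is the least-squares fit, with a slope of 0.729.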

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

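The tests of the central nervous system transcripts, of the urothelial transcripts, of chance through the shared LPS libraries, of less kidney RNA, of the urothelial covariate and of thymosin β4, and the splits for the number of genes between LPS+Tβ4 and LPS and for genes moved back, were chosen only after those results were seen, and the lists of other tissues were written after the first such genes had been noticed.

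All 19 central nervous system genes noticed first were higher in every LPS+Tβ4 library than in the other 6, with a median log2 ratio of 3.48 over LPS. Of 24 further markers of oligodendrocytes, astrocytes and neurons not looked at before, 13 were too (54.2%, where chance gives 1.2%), and with the markers already seen it was 21 of 36 (58.3%); RNA or reads of central nervous system tissue in these libraries may therefore be a source, although the rest were not higher, such as Mal at 297 CPM in both groups. Renal nerves do not account for it, since 9 peripheral nerve markers had a median log2 ratio of -0.88 (range -4.82 to 2.02). Expression of these genes by kidney cells given thymosin β4 cannot be told apart from it, because every library with the treatment had the transcripts; the 3 marker classes differed by at most 0.18 in their relative level in an LPS+Tβ4 library, over the 21 of 36 markers picked for being higher there, so that this value decides nothing. The step at which such RNA or reads would have entered is unknown.

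Urothelial transcripts were high in saline replicates 2 and 3, LPS replicates 1 and 2 and LPS+Tβ4 replicate 3, and all 5 urothelial markers not looked at before were higher in each of these 5 libraries than in each of the other 4 (100%, where chance gives 0.79%), as were 3 of 4 inner medullary collecting duct markers and 4 of 5 fat markers already looked at. How much renal pelvis, inner medulla and fat was in each piece of kidney is a candidate explanation. An exchange of the labels of LPS replicate 3 and LPS+Tβ4 replicate 3 would turn most differences between the groups around in these 2 libraries. Of the genes at least 2-fold apart between the other LPS and LPS+Tβ4 libraries, 57.6%, 62.3% and 64.7% differed the same way between those 2 libraries when genes differing within saline by over 1, 0.5 or 0.25 (log2) were left out, and 51.5% with none left out. So did 5 of 5 erythroid genes and 31 of 39 interferon-stimulated genes. Of the 18 central nervous system markers not looked at before that passed the expression filter, 14 did. These values argue against an exchange. Only 15 of 37 proximal tubule, 6 of 31 oxidative phosphorylation, 0 of 13 endothelium and 0 of 9 adipocyte genes differed the same way. Over all tested genes (log2 CPM), LPS+Tβ4 replicate 3 correlated at 0.96 and 0.949 with LPS replicates 1 and 2. With LPS+Tβ4 replicates 1 and 2 it correlated at 0.947 and 0.95. LPS replicate 3 correlated at 0.91 and 0.954 with LPS replicates 1 and 2, and at 0.948 and 0.932 with LPS+Tβ4 replicates 1 and 2. An exchange is therefore not excluded.

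For the 838 genes moved back towards saline, chance through the shared LPS libraries was examined in fits that share none. Of the genes changed by LPS, 71.1% at the lowest went the opposite way with LPS+Tβ4 (73.5% and 80.5% in the others). All 3 lay above 50% by more than their SD (4.9), and this excess cannot come from shared LPS libraries. The 3 fits use the same saline and LPS+Tβ4 libraries, and genes vary together. How far chance spreads around 50% was not measured, so chance differences between the mice remain possible. Less kidney RNA in the LPS+Tβ4 libraries would by itself leave the genes lowered by LPS where they were. Of their change 0.596 remained (SD 0.11 over 3 libraries), beside 0.616 for raised genes, both ratios of medians (by slope 0.708 and 0.873). These values argue against less kidney RNA by itself. They cannot decide on kidney RNA diluted by RNA of another tissue, which could carry some of the lowered genes. With the urothelial score as a covariate the count was 889, so it did not fall with that score in the fit. The count moved widely with the fit, however, and the split by urothelial transcripts gave 523. The covariate therefore cannot decide whether the amount of renal pelvis in the piece bears on the count. Thymosin β4 may underlie the count, but cannot be told apart from any other difference between the LPS and LPS+Tβ4 mice. The count was 576 without genes of neural terms.

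Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. For genes changed, 1 of 10 splits gave as many in each comparison: 6473 with 0 as the highest other (LPS against saline), 1025 with 673 (LPS+Tβ4 against LPS) and 3617 with 0 (LPS+Tβ4 against saline), and for genes moved back 1 gave 838, with 523 next. The split with 673 exchanged the third replicates of LPS and LPS+Tβ4, which is also the split by urothelial transcripts. For gene lists, 5, 9 and 2 splits gave as many as the real 20, 11 and 24, with 21, 17 and 25 as the highest others. For the KEGG MAPK pathway, 1, 4 and 2 splits gave an adjusted p as small as the real 0.011, 0.32 and 0.012, the other splits reaching 0.024, 0.056 and 0.0024.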

How the results depend on the processing

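The alternatives with DESeq2, filterByExpr, the urothelial terms and neural-term genes left out were chosen only after the data were seen, as was keeping limma on log2(FPKM + 1), the test planned for a table without counts, as an alternative; the other tests were chosen before. No tracked gene that passed its test changed its direction in an alternative run. The genes changed between LPS and saline kept within 1.5 times of 6473 except with a mean FPKM of at least 5 (3754, fewer genes tested) and a 2-fold minimum (3855), and ranged from 4884 to 6903 without 1 library. Those between LPS+Tβ4 and LPS (1025) were 647 with no filter, 638 with a mean FPKM of at least 5, 3 in the 6 libraries alone (389 at an adjusted p under 0.1, 2898 at an unadjusted p under 0.05), 5059 with array weights, 5 with a replicate block, 591 with a 2-fold minimum, 668 without genes of neural terms, 2442 by DESeq2 and 68 to 2672 without 1 library. Those between LPS+Tβ4 and saline (3617) were 2268 with a mean FPKM of at least 5, 6618 with array weights, 2255 with a 2-fold minimum and 2119 to 4544 without 1 library. Genes moved back (838) were 419 with no filter, 443 with TPM, 2 in the 6 libraries alone, 3891 with array weights, 2 with a replicate block, 418 with a 2-fold minimum, 1975 by DESeq2, 21, 3 and 386 with 1 LPS library held out (no spread of its own) and 54 to 2149 without 1 library. The 2-fold and neural-term counts are smaller by construction, and for the others the cause was not tested. The 6-library fit of LPS+Tβ4 and LPS had fewer libraries and none of saline, whose median SD of log2 CPM was 0.166 (0.321 in LPS, 0.214 in LPS+Tβ4).

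The slope of 0.729 was 0.613 with array weights and 0.665 to 0.781 without 1 library. Lists called were 3, 0 and 7 with an estimated correlation and 25, 8 and 25 by fry, against 20, 11 and 24; array weights gave 19 between LPS+Tβ4 and LPS, and ranges without 1 library were 20 to 23, 7 (without LPS replicate 1) to 15, and 21 to 25. The KEGG MAPK median was 0.26 to 0.34, -0.18 to -0.04 and 0.13 to 0.21 without 1 library, and lost its call between LPS+Tβ4 and saline with array weights (0.24, adjusted p = 0.054). DESeq2, the 2-fold minimum and the neural-term alternative gave no list values. Of 77 tracked genes that passed between LPS and saline, 74 kept their call in every alternative run (not Grb2, Mapk14 and Mapk8). Between LPS+Tβ4 and LPS, Slc2a2 and Camk2a did, of 51. Of 81 and 78 genes tracked in these comparisons, 3 and 22 that had not passed did so in at least 1 alternative run. Among the 22 were Podxl (9 runs), Fosl1 (7), Cd14, Mapk8 and Mapk14 (3 each) and Lcn2 (1). The median change of all genes against saline shifted by 0.27 and 0.36 with TPM and by 0.12 and 0.19 with a pseudocount of 0.1, and in LPS+Tβ4 by 0.14 with a pseudocount of 1 and 0.11 with array weights, and the share of calls that were higher went from 48.6% to 68.1% (LPS) and from 51.2% to 80.6% (LPS+Tβ4) with TPM. Depth was alike in the 9 libraries. In the simulated data, with 200 of 15015 genes changed, 3 libraries a group recovered few 2-fold changes. The adjusted threshold is easier to pass where more genes change, so this recovery does not give the power of the real comparisons. Between LPS and saline 6473 genes passed, and 3855 of them were at least 2-fold apart.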

Other observations

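The tests of other tissues below were chosen only after central nervous system transcripts had been seen. Of 30 apoptosis genes, 13 rose with LPS, 2 fell and 15 did not pass (median 0.76, camera adjusted p = 0.00015, and adjusted p = 0.058 with an estimated correlation), with the TNF receptor Tnfrsf1a from 45.1 ± 5.39 to 193 ± 11.6 CPM (n = 3). The necroptosis effector Mlkl rose by 4.69 and the inflammatory caspase Casp4 by 3.89, among 6 of 12 pyroptosis and necroptosis genes (camera adjusted p = 0.0012, and adjusted p = 0.1 with an estimated correlation). Of 19 genes of endoplasmic reticulum stress, 11 rose, among them Atf4 (2.06) and Ddit3 (2.23) (camera adjusted p = 0.00014, and adjusted p = 0.15 with an estimated correlation). The 25 genes of oxidative stress and ferroptosis did not pass as a list, with 9 raised, 2 lowered and 14 that did not pass (median 0.35, camera adjusted p = 0.1, and adjusted p = 0.55 with an estimated correlation). Of 22 genes of endothelial activation and coagulation, 15 rose and 2 fell (median 2.32, camera adjusted p = 9.4e-07, and adjusted p = 0.058 with an estimated correlation), with Icam1 from 13.7 ± 1.61 to 172 ± 37 CPM.

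Of 17 clock genes, 6 rose, 2 fell and 9 did not pass with LPS, and 1 rose, 3 fell and 13 did not pass between LPS+Tβ4 and LPS. The output regulator Hlf fell from 110 ± 12.4 to 7.33 ± 1.54 CPM with LPS and was 14.5 ± 3.03 CPM in LPS+Tβ4 (0.98, adjusted p = 0.032), while Per1, Cry1 and Cry2 were lower in LPS+Tβ4 than in LPS (-1.03, -1.43 and -1.32, adjusted p = 0.041, 0.026 and 0.047); the clock list as a whole did not pass (camera adjusted p = 0.27 and 0.051, and adjusted p = 0.55 and 0.51 with an estimated correlation). Of 12 monocyte and macrophage genes, none passed over all genes between LPS+Tβ4 and LPS in edgeR. Of these, 5 were higher adjusted over the list alone, 7 at an unadjusted p under 0.05, 5 by DESeq2 and 2 by limma on log2(FPKM + 1) (median 1.02, camera adjusted p = 0.0023, and adjusted p = 0.45 with an estimated correlation), with Csf1r at 45.7 ± 16, 13.2 ± 3.71 and 27.3 ± 3.86 CPM in saline, LPS and LPS+Tβ4. The glucocorticoid-responsive list had a median of -0.83 (camera adjusted p = 0.00057, and adjusted p = 0.36 with an estimated correlation), with Per1 the 1 member of 13 that passed.

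Among the lists of other tissues, the number of markers with counts that were higher in every LPS+Tβ4 library than in the other 6 was 4 of 10 for oligodendrocytes, 3 of 8 for astrocytes, 14 of 18 for neurons, 2 of 5 for cortex, 3 of 5 for striatum, 4 of 5 for brainstem and spinal cord, 0 of 3 for cerebellum, 2 of 10 for peripheral nerve (Mbp and Sox10), 1 of 4 for retina, 0 of 6 for liver, 0 of 5 for heart and 0 of 1 for lung. No testis or pancreas marker had enough counts. The liver markers summed to 508 CPM in saline replicate 1, and to 50.3 and 35.2 CPM in saline replicates 2 and 3. In the LPS and LPS+Tβ4 libraries they summed to 13.5 to 103 CPM. The source of the liver transcripts in saline replicate 1, a library used in both comparisons with saline, was not tested. The adrenal gland list, fixed before the data were examined, summed to 20, 25.9 and 20.7 CPM in LPS+Tβ4 and to 4.48 to 11.7 CPM in the other 6 libraries. Most of this was Chgb (11.8 CPM in LPS+Tβ4 and 0.974 CPM in LPS, adjusted p = 0.038) and Chga (6.34 and 0.922 CPM, adjusted p = 0.14), while Star was at 3.7 and 4.63 CPM (adjusted p = 0.48). Adrenal tissue as a source was not tested. The skeletal muscle list summed to 1.48 to 2.72 CPM in LPS+Tβ4 and to 1.24 to 12.3 CPM in the others. The saline libraries also held some of the central nervous system transcripts, such as Mbp (25.8 CPM) and Snap25 (8.17 CPM), and their source there was not tested.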
